A study of Mus musculus with 4 samples.

How the data were processed

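RNA sequencing was done on effector T cells of NOD.Foxp3-GFP mice, a strain that develops autoimmune diabetes and carries a green fluorescent reporter for the regulatory T cell factor Foxp3. Per the labels, the mice were 6 to 9 weeks old, the tissue field names pancreatic islets and spleen, and the 4 library titles and the design text refer to islet effector T cells with high or low CD5, with 2 libraries in each group. The titles number the libraries 3 and 4 in each group. Whether a number marks cells from the same animals, and whether the authors' test took it into account, are not given in the sources used here. CD5 is a surface glycoprotein of T cells whose level is widely used as a readout of how strongly a T cell responds to self-peptides. Per the labels' protocols, cells were lysed in Triton X-100, RNA was reverse transcribed, the cDNA was amplified, and libraries were made with Nextera XT, a transposase-based kit that does not mark strand. Reads from overlapping genes on opposite strands were therefore not separable by strand.

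Per the submitters' processing notes, the tools were TopHat 1.0.0 and Cufflinks, and the build was mm10; the version of Cufflinks and the gene annotation are not given in the sources used here. The values come from a single table of the authors whose column names, per the file headers, are those of a Cuffdiff gene test. For each gene the authors deposited 1 FPKM value (fragments per kilobase of transcript, scaled to mapped fragments) for CD5 low and 1 for CD5 high, a log2 fold change, a test statistic score, a p-value and a q-value. The deposited log2 fold change equals the log2 ratio of the FPKM values, CD5 high over CD5 low, to within 5.1e-05, so no pseudocount was added. How libraries were scaled, which libraries entered each group value, and whether the test was two-sided are not given in the sources used here.

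The table held 7404 gene rows, and 1 further line is not analysed here. Of these rows, 7252 had the status OK and are called tested below, and 152 had the status LOWDATA and no test, 117 of them with both values at 0. The smallest p-value was 5e-05 and was shared by 33 genes, so these genes cannot be ranked among themselves. The smallest q-value, 0.0110, corresponds to an adjustment over 7253 tests. Every tested gene reached at least 6.82 FPKM in one of the groups, so genes of low expression are not analysed here. In 13 rows a spreadsheet had turned the gene name into a date, 43 rows named more than 1 gene, and 15 tested rows were listed at 0 in 1 group and had no finite fold change. None of these 15 is given a fold here.

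Because the table holds 1 combined value per group, no SD, standard error or n can be attached to a value, and the depth of the libraries is unknown. The values are already combined over libraries and scaled by gene length, and rows of few reads were not tested, so no whole-read step was sought. The labels do not say that the libraries came from separate animals, so the authors' p-values cannot be read as measuring the spread between animals. Which variation they do measure is not given in the sources used here, and it may be technical. The limma test on single libraries, the camera tests of gene lists, the correlations between replicates, the replicate block and the leave-one-out fits that had been planned could not be run. As laid down before the data were examined for this case, the authors' comparison is described instead. A gene is said to have changed, risen or fallen when the authors' q-value was under 0.05, which coincided with the authors' own significance flag in all 55 cases. Direction is CD5 high relative to CD5 low throughout.

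A set of 28 gene lists (611 genes), 19 for T cell states and functions and 9 for other cell types and RNA quality, was fixed before the data were examined. For each list the number of tested and changed members was counted, over all genes and with the authors' p-values adjusted by Benjamini-Hochberg over the list alone. For the 22 lists with at least 3 tested members, the median log2 fold change was set against the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins. The resulting percentile describes these group values and is not a p-value, since genes are not replicates. On simulated lists of 20 genes drawn from the 7237 tested genes with a finite fold change, a shift of 0.5 (log2) placed 40 of 40 lists above the central 95% of matched medians, a shift of -0.5 placed 40 of 40 below it, and a shift of 0.25 placed 32 of 40 above it. With no shift, 1 of 40 lay above it and 2 of 40 below. Fold changes were shuffled over genes in this simulation, so list members varied independently. How often lists of genes that vary together would leave the range without a difference was not tested. The matched range given below is this central 95%.

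The genes named were Cd5, the 12 changed genes with the largest rise and the 12 with the largest fall (predicted genes, Rik clones and small RNA genes left out), and for each list its changed members if 6 or fewer, or otherwise the 4 with the smallest p; where a list had none, the 2 members with the highest mean FPKM. The condition that single libraries of the groups do not overlap could not be applied. Other genes are given as values or chosen after their values were seen, as stated where they appear. One list member is not reported here by name. The alternatives tried were pseudocounts of 0.1 and 1, mean FPKM of at least 1, 5 or 20, quantile normalization, median-ratio scaling, another q-value limit (0.10), a normal p-value computed from the authors' test statistic, removal of the marker genes of other cells, and removal of regulatory T cell list members from other lists. Coordinates are the authors' loci on mm10 with the start written 1-based. By symbol, 93.6% of rows matched GENCODE M21, which uses the same assembly, and 99.5% of these overlapped the matched gene. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.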

Results

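The series compared effector T cells sorted by high or low CD5 from the islets of NOD mice, to ask how their transcriptomes differ. There were 2 libraries per group. The authors' deposited table gives 1 combined FPKM value per group for 7252 tested genes, with the authors' test of the difference. Values per library were not analysed here, so the values below carry no SD and the sequencing depth is unknown. Median expression of the tested genes was 20.2 FPKM in CD5 low and 20.5 FPKM in CD5 high, and the median log2 fold change was -0.01. The fold change was under 2-fold for 95.6% of the tested genes with a finite fold.

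In the authors' deposited table, 55 of 7252 genes (0.758%) differed between CD5 high and CD5 low cells at q under 0.05, 39 of them higher and 16 lower in CD5 high. The genes that rose included the co-inhibitory receptors Tigit, Lag3 and Ctla4, the cytokine Il10, the costimulatory receptors Tnfrsf4 (OX40) and Tnfrsf18 (GITR), and the proliferation genes Mki67 and Top2a. Those that fell included the chromatin organizer Satb1, the interferon-inducible GTPase Igtp and the MHC class II genes H2-Ab1, H2-Aa and H2-Eb1. The finite rises ranged from 0.73 to 6.52 on the log2 scale with a median of 1.22, and the finite falls from -0.74 to -2.39 with a median of -1.10. The largest rise was that of the insulin gene Ins1. Of the 55 genes, 7 belong to the fixed marker lists of other cells, the class II genes among them. The regulatory T cell list was higher in CD5 high as well (median log2 fold change 1.04). Which cells carried these differences stays open. At an unadjusted p under 0.05 the table held 746 genes (10.3% of those tested), 405 higher and 341 lower.

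**Figure D1:**
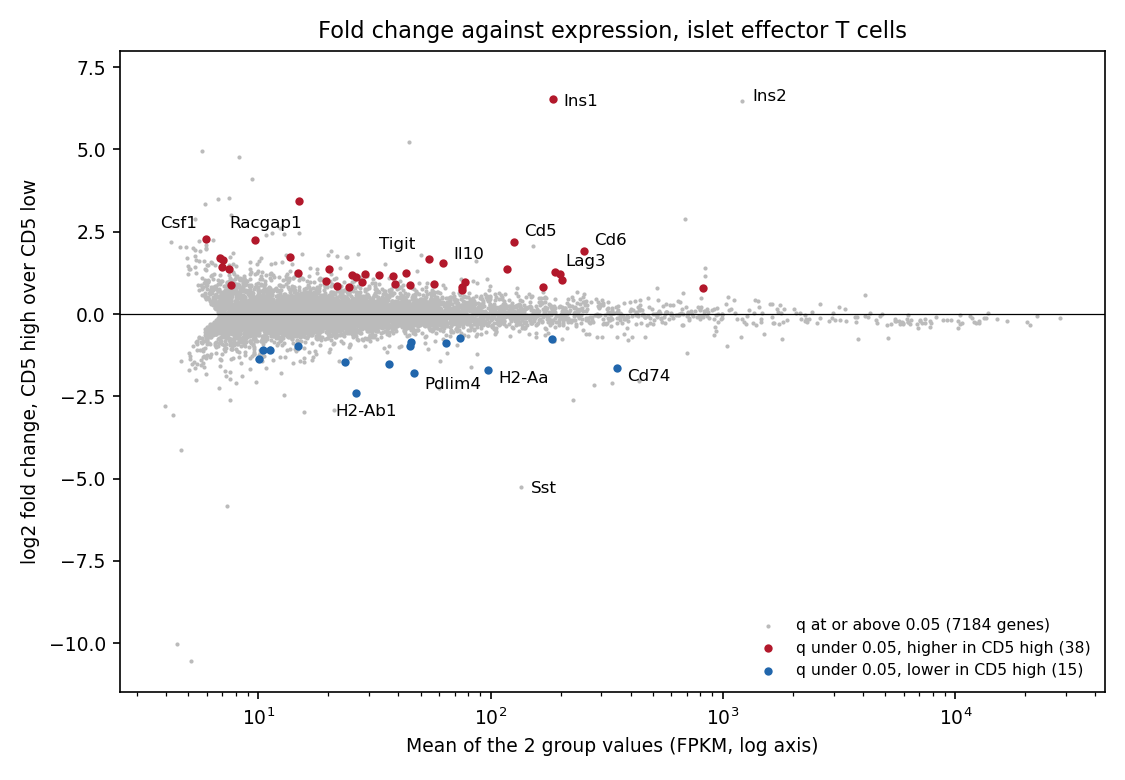
Log2 fold change (CD5 high over CD5 low) against the mean of the group values (FPKM, log axis) for every tested gene with a finite fold change; each point is 1 gene, red for genes that rose and blue for genes that fell at q under 0.05 in the authors' deposited table, gray for the rest. The 38 red points reach from 0.73 to 6.52 and the 15 blue points from -0.74 to -2.39; Fcer1g and Hist1h1b, listed at 0 in 1 group, are not drawn.

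Cd5 itself, the gene for the sorted protein, was 45.4 FPKM in CD5 low and 206 FPKM in CD5 high in the authors' deposited table, a 4.54-fold difference (q = 0.0110). Its direction matches the group names and is no finding, since the cells were selected on CD5. Cd5 lies at chromosome 19, 10718143 to 10738974 (mm10), and its neighbour Cd6, which encodes a related scavenger receptor of T cells, lies at 10789339 to 10830058. In the authors' deposited table Cd6 rose 3.76-fold, from 106 to 399 FPKM (q = 0.0110).

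Among genes of T cell receptor signal strength and activation, 5 of 25 tested members rose and none fell: Cd5, Cd6, Tnfrsf4, Spry1 and Tnfrsf18. Cd5 was the basis of the sort, so its place in this list's counts is no finding. Tnfrsf4 went from 65.8 to 169 FPKM (2.56-fold, q = 0.0110) and Spry1, a feedback inhibitor of receptor tyrosine kinase and T cell receptor signalling, from 11.3 to 29.0 FPKM (2.56-fold, q = 0.0253) in the authors' deposited table. Tnfrsf18 went from 122 to 213 FPKM (1.75-fold, q = 0.0462). With p-values adjusted over the list alone, 8 members were higher and 1, Cd40lg, was lower. Chosen after their values were seen, the list's Nr4a, Egr and Cd69 members did not pass the test in the authors' deposited table and lay in both directions. Nr4a1 had 97.0 FPKM in CD5 low and 88.8 FPKM in CD5 high (q = 0.878), Egr1 had 49.9 and 40.9 FPKM (q = 0.683) and Cd69 had 160.2 and 126 FPKM (q = 0.571). Nr4a2 had 22.9 and 31.4 FPKM (q = 0.521), Egr2 had 25.1 and 27.1 FPKM (q = 0.922) and Nr4a3 had 16.5 and 17.1 FPKM (q = 0.979). The list's median log2 fold change was 0.40, above the range of matched random lists (-0.14 to 0.15). Without Cd5 and the members shared with the regulatory T cell list it was 0.13 over 21 genes, inside the matched range of -0.15 to 0.16.

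Co-inhibitory receptors and exhaustion-associated genes were higher in CD5 high in all 13 tested members, and 5 of these rose at q under 0.05. In the authors' deposited table Tigit rose 3.19-fold, from 26.0 to 83.0 FPKM (q = 0.0110), Lag3 rose 2.43-fold, from 111 to 269 FPKM (q = 0.0110), and Ctla4 rose 2.06-fold, from 132 to 272 FPKM (q = 0.0110). The ligand gene Cd200 rose 2.27-fold (20.2 to 45.9 FPKM, q = 0.0186), and Rgs16, a regulator of G protein signalling, rose 1.95-fold (52.9 to 103 FPKM, q = 0.0110). Pdcd1, which encodes PD-1, had 31.6 and 52.5 FPKM and did not pass the test (q = 0.210). When adjusted over the list alone, 7 members were higher, Pdcd1 and Tox2 among them. The list's median was 0.73, against -0.19 to 0.21 in matched lists, and 0.66 without Ctla4, which the regulatory T cell list also holds. Regulatory T cell markers had higher values in CD5 high as well, with Foxp3 at 1.10 and 12.3 FPKM (q = 0.298) and Ikzf2 2.19-fold higher (q = 0.0110) in the authors' deposited table. Lag3 lies at chromosome 6, 124904359 to 124911705, and Tigit at chromosome 16, 43648861 to 43664184 (mm10).

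The anergy list held 3 genes that rose among 14 tested. In the authors' deposited table the anti-inflammatory cytokine Il10 went from 31.9 to 93.4 FPKM (2.93-fold, q = 0.0110), and Folr4, now named Izumo1r and coding for folate receptor 4, from 120 to 278 FPKM (2.32-fold, q = 0.0110). The third was Lag3, which this list shares with the previous one. There were 5 higher members adjusted over the list alone, and the median was 0.28 against -0.19 to 0.19 in matched lists. The median was 0.19 and inside its matched range with genes under a mean of 20 FPKM left out, and likewise 0.19 without Nrp1, the tested member shared with the regulatory T cell list. Foxp3 and Ikzf2 had higher values in CD5 high beside this list too, with log2 fold changes of 3.49 (q = 0.298) and 1.13 (q = 0.0110) in the same table.

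All 9 tested members of the regulatory T cell list were higher in CD5 high, and 4 rose: Ctla4, Tnfrsf4, Tnfrsf18 and Ikzf2, which encodes the transcription factor Helios. Ikzf2 went from 16.6 to 36.3 FPKM (2.19-fold, q = 0.0110) in the authors' deposited table. Foxp3, the lineage factor of regulatory T cells, was 1.10 FPKM in CD5 low and 12.3 FPKM in CD5 high and did not pass the test over all genes (q = 0.298). Foxp3 was among the 8 members that were higher adjusted over the list alone. The median was 1.04, against -0.26 to 0.27 in matched lists.

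Genes of T follicular helper cells included 1 of 14 that rose, Cd200, while 13 of 14 had a higher value in CD5 high. Adjusted over the list alone, 10 members were higher, with Cxcr5 at 12.2 and 24.8 FPKM (q over all genes 0.0975) and Maf at 115 and 177 FPKM (q over all genes 0.0952) in CD5 low and CD5 high of the authors' deposited table. The median was 0.66, against -0.19 to 0.21 in matched lists. The regulatory T cell markers Foxp3 (q = 0.298) and Ikzf2 (q = 0.0110) also had higher values in CD5 high.

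Among cell cycle genes, 4 of 17 tested members rose and none fell. The proliferation marker Mki67 rose 3.27-fold, from 3.22 to 10.5 FPKM (q = 0.0110), the topoisomerase gene Top2a 2.61-fold, from 4.13 to 10.8 FPKM (q = 0.0427), the replication helicase subunit gene Mcm6 2.22-fold, from 23.5 to 52.3 FPKM (q = 0.0110), and Hmgb2 1.66-fold, from 56.4 to 93.7 FPKM (q = 0.0462), in the authors' deposited table. A total of 8 members were higher adjusted over the list alone, and the median was 0.77 against -0.25 to 0.25 in matched lists. The regulatory T cell list was higher in CD5 high too (median 1.04), and which cells carried the cell cycle genes was not tested. Outside the list, Racgap1, required for cytokinesis, rose 4.71-fold (3.38 to 15.9 FPKM, q = 0.0253), and the linker histone gene Hist1h1b was listed at 0 in CD5 low and at 14.0 FPKM in CD5 high (q = 0.0110) in the authors' deposited table.

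**Figure D2:**
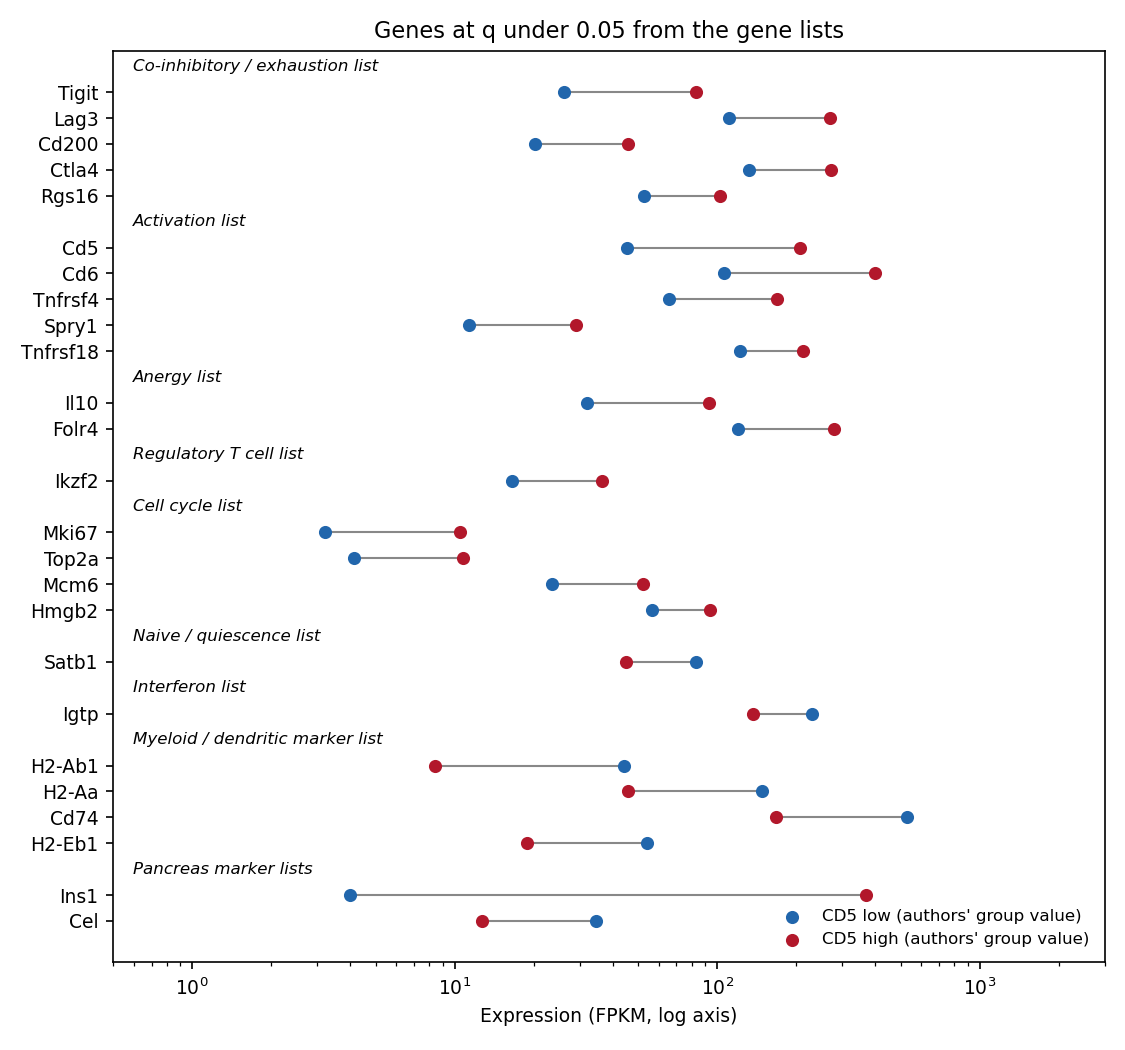
Group values (FPKM, log axis) of changed genes from the fixed lists in the authors' deposited table, blue for CD5 low and red for CD5 high, with a gray line joining the values of 1 gene. A gene in more than 1 list is drawn once, and the changed list members Ahr and Fcer1g are not drawn. Values of the co-inhibitory, activation, anergy, regulatory and cell cycle genes lie to the right in CD5 high (Tigit, 26.0 to 83.0 FPKM), and those of Satb1, Igtp and the class II genes lie to the left (H2-Aa, 149 to 45.6 FPKM).

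Genes of naive and quiescent T cells had lower values in CD5 high in 23 of 25 tested members, and 1 of these fell. Satb1 went from 83.2 to 45.0 FPKM (1.85-fold lower in CD5 high, q = 0.0110) in the authors' deposited table. Adjusted over the list alone, 5 members were lower. Besides Satb1 these included the interleukin-7 receptor gene Il7r (208 and 134 FPKM in CD5 low and CD5 high, q over all genes 0.0714), the transcription factor gene Lef1 (455 and 298 FPKM, q 0.0975) and the chemokine receptor gene Ccr7 (210.0 and 142 FPKM, q 0.169) in the authors' deposited table. The list's median was -0.37, against -0.14 to 0.13 in matched lists. The regulatory T cell list went the other way (median 1.04), and whether regulatory T cells contribute to the lower naive values was not tested.

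Interferon-stimulated genes had lower values in CD5 high in 20 of 25 members, of which Igtp fell, from 230 to 137 FPKM (1.68-fold, q = 0.0110) in the authors' deposited table. Adjusted over the list alone, 2 members were lower and 1, Ifi27l2a, was higher, and the median was -0.25 against -0.15 to 0.15 in matched lists. Of the Th1 and cytotoxic list, none of 23 members changed at q under 0.05, and 10 had an unadjusted p under 0.05. The most abundant were Ccl5, with 1020 FPKM in CD5 low and 1106 FPKM in CD5 high (q = 0.884), and Nkg7, with 397 and 558 FPKM (q = 0.332), in the authors' deposited table. Adjusted over the list alone, 2 members were higher and 1 lower, and the median of 0.32 lay above the matched range of -0.17 to 0.16.

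In the Th17 list, 1 of 3 tested members rose. This was the aryl hydrocarbon receptor gene Ahr, from 8.85 to 20.8 FPKM (2.35-fold, q = 0.0110) in the authors' deposited table, while the list's median was -0.24 and lay within the matched range. In the Th2 list none of 5 members changed, with Gata3 at 45.8 and 54.7 FPKM (q = 0.713) and Ccr8 at 36.7 and 70.3 FPKM (q = 0.123). In that list 2 members had an unadjusted p under 0.05, and the same number were higher adjusted over the list alone.

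No member changed at q under 0.05 in 8 further lists. The T cell receptor complex list (26 members, median 0.11) had 3 members at an unadjusted p under 0.05, with Lat at 986 and 991 FPKM and Cd3g at 744 and 857 FPKM in CD5 low and CD5 high of the authors' deposited table. The trafficking list (19 members, median 0.02) had 7 such members, 4 higher and 3 lower when adjusted over the list alone, and its most abundant genes were Itgb7 at 342 and 315 FPKM and Cxcr4 at 287 and 289 FPKM. The survival list (20 members, median 0.07) had 2, with Il7r as above and Mcl1 at 116 and 99.1 FPKM. Glycolysis genes (16 members, median 0.06) had 2, with Gapdh at 279 and 361 FPKM and Ldha at 208 and 215 FPKM. NF-kB targets (17 members, median 0.14) had 1, with Nfkbia at 328 and 326 FPKM and Ltb at 347 and 280.0 FPKM. The medians of these 5 lists lay within their matched ranges. Adjusted over the list alone, 2 receptor complex genes (Zap70 higher and Grap2 lower), 1 survival gene (Il7r, lower), 1 glycolysis gene (Hif1a, higher) and 0 NF-kB targets passed.

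The medians of the other 3 of these lists lay outside their matched ranges, with 0 members past the threshold adjusted over the list alone. Oxidative phosphorylation genes (37 members, 2 at an unadjusted p under 0.05) had a median of 0.08 and a matched upper limit of 0.06, with Cox6a1 at 1236 and 1349 FPKM and Atp5h at 1206 and 1086 FPKM in the authors' deposited table. Immediate early and dissociation stress genes (22 members, 1 at that p) had a median of -0.18 and a matched lower limit of -0.16, with Hspa8 at 2283 and 2062 FPKM and Hsp90aa1 at 1793 and 1482 FPKM. Ribosomal protein genes (49 members, 1 at that p) had lower values in CD5 high in 44 members, with a median of -0.21 against a matched lower limit of -0.13, and Rps29 at 29533 and 26887 FPKM and Rps14 at 23359 and 18535 FPKM. After quantile normalization the ribosomal median was -0.03 and the oxidative phosphorylation median 0.06, both inside their matched ranges. That of the receptor complex list was then 0.13, above its range.

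**Figure D3:**
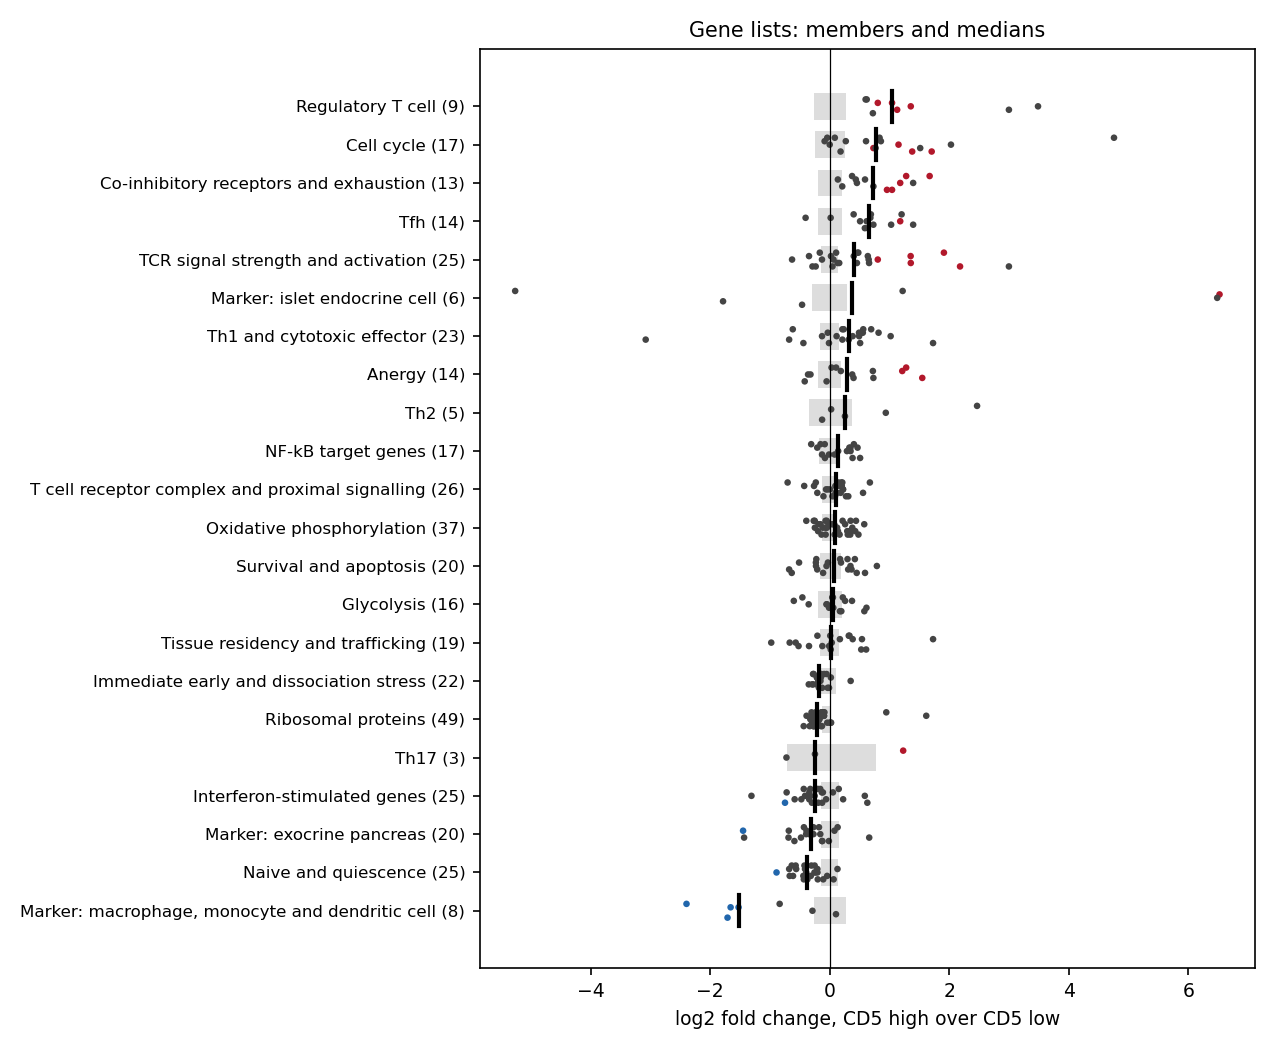
Log2 fold change (CD5 high over CD5 low) of each tested list member (points; red and blue for genes that rose or fell at q under 0.05), the list median (black bar) and the central 95% of medians of 10000 matched random lists (gray band), with the number of tested members in parentheses. The regulatory T cell median stands at 1.04 and the naive median at -0.37, outside their bands; Fcer1g has no finite fold and is not drawn.

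Markers of other cells differed between the groups as well. In the macrophage, monocyte and dendritic cell list 5 of 8 tested members fell in CD5 high. By the authors' deposited table H2-Ab1 went from 44.3 to 8.44 FPKM (5.26-fold lower, q = 0.0186), H2-Aa from 149 to 45.6 FPKM (3.27-fold lower, q = 0.0110), H2-Eb1 from 54.1 to 18.8 FPKM (2.87-fold lower, q = 0.0110) and Cd74, the class II invariant chain, from 530 to 168 FPKM (3.15-fold lower, q = 0.0110). Fcer1g, the Fc receptor gamma chain, was 15.8 FPKM in CD5 low and listed at 0 in CD5 high (q = 0.0110). The list's median was -1.52 against -0.27 to 0.27 in matched lists, Fcer1g left out. The remaining members were Cst3, at 295 and 242 FPKM, Apoe, at 11.9 and 6.65 FPKM, and Ctss, at 133 and 144 FPKM, and none of these passed the test.

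Pancreatic transcripts were also present in the T cell libraries. By the authors' deposited table the insulin gene Ins1 was 4.003 FPKM in CD5 low and 368 FPKM in CD5 high (92.0-fold, q = 0.0186), and its paralog Ins2, with which it can share reads, was 26.7 and 2395 FPKM (q = 0.193). The somatostatin gene Sst had its higher value in CD5 low, with 263 and 6.86 FPKM (q = 0.0714). Of the 6 tested endocrine members 3 were higher and 3 lower, with 1 that passed over all genes and 2 higher and 1 lower adjusted over the list alone. Their median was 0.38, above the matched range of -0.29 to 0.29, and without Ins1 and Ins2 the median of the other 4 was -1.12, below a matched range of -0.40 to 0.40. Among 20 exocrine genes 17 had lower values in CD5 high and 1 fell, the lipase gene Cel (34.6 to 12.7 FPKM, 2.73-fold lower, q = 0.0186). The exocrine median was -0.31, against -0.15 to 0.15 in matched lists, and 2 members were lower adjusted over the list alone.

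Other marker lists had too few tested members for a median. No CD8 T cell and no erythroid or platelet marker was among the tested genes. The B cell list was represented by Cd79b (11.0 and 14.0 FPKM in CD5 low and CD5 high, q = 0.862), the list of gamma-delta, NKT and NK cells by Tyrobp (21.8 and 3.94 FPKM, q = 0.480) and the endothelial and stromal list by Pecam1 (21.3 and 16.6 FPKM, q = 0.687) in the authors' deposited table. Tyrobp had an unadjusted p of 0.0478 in the authors' test, which adjustment over its list of 1 tested gene leaves as it is. For RNA quality, only Malat1 (2420 and 2155 FPKM) and Neat1 (107 and 118 FPKM) were tested. Without the marker genes of other cells, 44 genes remained past the threshold after renewed adjustment, 34 higher and 10 lower, all of them among the 55. Tnfrsf18, Hmgb2, Csf1 and Ptms were then just outside it, each at an adjusted value of 0.0526.

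Among changed genes with the largest rises outside these groups, Csf1, which encodes macrophage colony-stimulating factor, rose 4.88-fold (2.02 to 9.87 FPKM, q = 0.0462), Sec14l1 3.29-fold (6.38 to 20.97 FPKM, q = 0.0110) and the microtubule-binding protein gene Mapre2 3.12-fold (3.43 to 10.7 FPKM, q = 0.0322) in the authors' deposited table. Among the largest falls, Pdlim4 was 3.43-fold lower in CD5 high (72.3 to 21.05 FPKM, q = 0.0110), Cpne4 2.58-fold (14.5 to 5.63 FPKM, q = 0.0378), Lyst, a regulator of lysosome-related granules, 2.14-fold (15.3 to 7.13 FPKM, q = 0.0110) and Crim1 2.14-fold (14.3 to 6.68 FPKM, q = 0.0427). The phosphodiesterase gene Pde3b was 1.96-fold lower (19.7 to 10.04 FPKM, q = 0.0253), as was the selenoprotein P gene Sepp1 (59.5 to 30.4 FPKM, 1.96-fold, q = 0.0110). With 1 combined value per group it could not be seen whether a difference was present in each library, and the calls above rest on the authors' p-values. When a two-sided normal p-value was computed from the authors' test statistic instead, 14 genes passed after Benjamini-Hochberg adjustment, 28.6% of them higher in CD5 high. Of the 55 genes only Cd5, Cd6, Ins1, Cd74 and H2-Aa were among them. Small RNA genes made up 7 of the 14, all lower in CD5 high and none at an unadjusted p under 0.05 in the authors' test. The deposited p-values are not normal tail areas of the statistic, so this alternative cannot show which calls hold.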

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

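The settings chosen after the data were seen were the q-value limit of 0.10, the normal p-value, the mean of 20 FPKM and the removal of marker genes or of regulatory T cell list members. No paired analysis was possible because the table holds 1 combined value per group, although the titles share the numbers 3 and 4 across groups, and for the same reason the fits without single replicates, the variance trend, the limma and count models, the camera tests and the agreement of replicates were not run. The count of 55 genes was the same with a mean FPKM of at least 1 (which removed no tested gene) or 5, was 42 of 3703 genes (38 of the 55) with at least 20, and was 44 without marker genes of other cells. It was 93 at q under 0.10. A two-sided normal p-value from the authors' test statistic, adjusted by Benjamini-Hochberg over 7237 genes, gave 14 genes, 28.6% of them higher in CD5 high against 70.9% in the main count. Only 5 of the 55 were among these (Cd5, Cd6, Ins1, Cd74 and H2-Aa), 7 of the 14 were small RNA genes, and the others were Ins2 and Sst; 31 of 60 named genes (Cd5 not counted) passed only by the authors' p-value. Of the 55 genes, 6 have a deposited statistic under the two-sided normal limit of 1.96 in size, so the deposited p-values are not normal tail areas of the deposited statistic. How they were obtained is not given in the sources used here, so the normal p-value cannot show which of the 55 calls hold. The statistic had an SD of 0.776 over the tested genes with a finite value. Pseudocounts and scaling leave the authors' p-values as they are, so they could not move the count. Pseudocounts of 0.1 and 1, quantile normalization and median-ratio scaling changed no direction among the called genes named, and Cd5 had a log2 fold change between 2.16 and 2.19 under them. Of 22 lists, 15 lay outside their matched range, 9 above and 6 below, and 14 did after quantile normalization. By chance 1.1 would if the genes within a list varied independently, which was not tested. Members of a list may vary together, so these counts do not show how many lists differ beyond chance. The anergy list fell inside its range (median 0.19) when genes under a mean of 20 FPKM were left out, and the anergy (0.19) and activation (0.15) lists did without members of the regulatory T cell list, while the co-inhibitory list (0.66) stayed above its range. Only Ctla4 was taken from the co-inhibitory list, so this removal cannot separate its higher values from regulatory T cells. Depth cannot be read from these values, and genes under about 6.82 FPKM in the higher group were not tested, which limits what the marker lists of rare cells can show.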

Other observations

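The tests of regulatory T cell genes, of activation genes, of beta cell and exocrine genes, and of neighbouring genes were chosen after some of the values had been seen; those of myeloid, B cell and endocrine genes were set out before. The rule for reading all of these medians was itself changed after the first results were seen. At first a median counted against an explanation only if it lay on the other side of 0 by more than the SD of its members, and it was then set against the matched range instead. Under the first rule the endocrine result (median -1.12, SD 2.75) and the exocrine result (median -0.31, SD 0.482) would have decided nothing; the readings of the other medians are the same under both rules. Outside every fixed list lay 28 of the 55 changed genes, 20 higher and 8 lower in CD5 high. Chosen after their values were seen, Lgals1, which encodes the lectin galectin-1, rose from 606 to 1043 FPKM (q = 0.0110), Tnfrsf1b, which encodes TNF receptor 2, from 19.0 to 37.1 FPKM (q = 0.0110) and Ptpn11, which encodes the phosphatase SHP-2, from 31.9 to 58.2 FPKM (q = 0.0110) in the authors' deposited table. The integrin gene Itga6 fell from 58.6 to 32.2 FPKM (q = 0.0322). A further 38 genes had q between 0.05 and 0.10, 23 higher and 15 lower. Among these Prdm1, which encodes Blimp-1, had 8.41 and 17.1 FPKM (q = 0.0553), Stmn1 had 18.3 and 52.3 FPKM (q = 0.0553), Icos had 100.1 and 156 FPKM (q = 0.0714) and Zap70 had 130 and 207 FPKM (q = 0.0747).

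The higher regulatory T cell genes in CD5 high may come from regulatory T cells in that sort, from stronger activation, or both. Foxp3, Ikzf2, Capg and Socs2, the tested members that no other T cell list holds, had a median log2 fold change of 0.88, at the 99.8th percentile of matched lists. These genes are among the 9 that make the pattern, so this restates it and does not test its source. Activation genes outside the regulatory list, Cd5 left out, had a median of 0.13, at the 95.7th percentile, which neither supports nor excludes activation as the source. A gate on the Foxp3 reporter would remove regulatory cells, but the labels give only the reporter genotype. Both explanations stay open, also for the co-inhibitory and anergy genes that rose, as does a difference that CD5 level itself marks. For the follicular helper, cell cycle and naive lists these sources were not tested and stay open as well.

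The lower class II genes in CD5 high may reflect antigen-presenting cells in the CD5 low sort. The tested myeloid and dendritic markers other than class II, Cd74 and Fcer1g (Cst3, Apoe and Ctss) had a median log2 fold change of -0.29, at percentile 7.41 of matched lists and inside their range, so this source is neither shown nor excluded. Of genes that myeloid cells also express, Fcer1g fell with the class II genes (15.8 FPKM in CD5 low, listed at 0 in CD5 high, q = 0.0110), and Tyrobp had 21.8 and 3.94 FPKM but did not pass the test (q = 0.480) in the authors' deposited table. The neutrophil transcript S100a8 lay in the other direction, with 2.31 FPKM in CD5 low and 86.6 FPKM in CD5 high, and did not pass either (q = 0.684). For B cells a single marker was tested, Cd79b, at 0.35, which is too few to decide, and expression of class II genes by the T cells themselves was not tested.

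The higher Ins1 and Ins2 in CD5 high were not matched by higher medians of the exocrine or the other endocrine genes. Exocrine genes had a median log2 fold change of -0.31 and the other endocrine genes (Iapp, Sst, Ppy and Scg5) one of -1.12, both below their matched ranges. Under the later rule this argues against more tissue of every kind and against endocrine RNA of all cell types. Under the first rule neither median decided anything. The matched ranges draw genes singly, while transcripts of 1 tissue may vary together, and none of these other endocrine genes passed the test over all genes. The endocrine prediction did not allow for material from 1 endocrine cell type, since Sst and Ppy belong to others than beta cells. Beta cell RNA alone remains a possible explanation. Iapp, taken as the 1 other tested beta cell gene, was at 1.22 (7.99 FPKM in CD5 low and 18.6 FPKM in CD5 high, q = 0.864). Its 2.33-fold difference was far smaller than the 92.0-fold of Ins1 and the 89.6-fold of Ins2, and this single gene cannot decide the question. Scg5, which is not assigned to 1 endocrine cell type here, was at -0.46 (q = 0.767), in the other direction. Whether the insulin reads came from 1 library could not be examined.

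Some changed genes lay side by side on chromosomes. There were 6 adjacent pairs, each with the same direction, where 10000 random draws held 0.411 on average and at most 5 (one-sided permutation p = 1e-04, the smallest these draws can give). These draws place genes singly and take no account of gene families. With Cd5, the sorted gene, left out and neighbours of a shared symbol stem never counted, in the data or the draws, 2 pairs were left (one-sided permutation p = 0.0525), so chance placement stays open for these. The pairs were H2-Ab1 with H2-Aa, H2-Aa with H2-Eb1, Tnfrsf4 with Tnfrsf18, Lag3 with Ptms, and the noncoding A430093F15Rik with Cd5 on one side and Cd6 on the other. A430093F15Rik went from 2.53 to 27.4 FPKM (q = 0.0253), lies 1972 bp from Cd5 and 3295 bp from Cd6, and is annotated on the opposite strand to both. The libraries do not mark strand, and A430093F15Rik lies past the 3' end of Cd6. Reads of A430093F15Rik could therefore not be told from reads running on from Cd6. The nearest tested genes beyond them had log2 fold changes of 0.42 (Ddb1, q = 0.478) and -0.15 (Tmem109, q = 0.923). Of the pairs, 3 join clustered paralogs, and how often such paralogs change together was not tested.

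Small nucleolar, microRNA and other small RNA genes were above 2-fold or listed at 0 in 1 group in 43.1% of 58 tested rows. Counted the same way, the share of other tested genes was 4.32%. Of the 58 rows, 12 were listed at 0 in 1 group and have no finite fold change, which raises the small RNA share. None of the 58 passed the test (0 also had an unadjusted p under 0.05 in the authors' deposited table). Snord42a was 5252 FPKM in CD5 low and listed at 0 in CD5 high (q = 0.736). S100a8, an abundant neutrophil transcript, had 2.31 and 86.6 FPKM in CD5 low and CD5 high (q = 0.684).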
